A study of Mus musculus with 6 samples.

How the data were processed

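The samples were 6 Affymetrix MOE430 2.0 arrays of RNA from cultured Eμ-Myc mouse lymphoma cells, 3 from cells sorted as dsRed2 positive and TTP-GFP negative and 3 from cells sorted as dsRed2 positive and TTP-GFP positive. RNA was purified with a NucleoSpin kit and biotin-labelled cRNA was made by in vitro transcription, per the labels' protocols. The deposited values are probe set intensity summaries on a linear scale, made with GCRMA (background adjustment from probe sequence, normalization across arrays and summary of the probes of a set) per the submitters' processing notes. Its version and settings were not given in the sources used here. That the scale is linear was read from the values, which are all positive with array medians of 10.02 to 10.83 and maxima of 98683 to 104453. GCRMA compresses values near the background, so low values have a small spread and folds that start there are understated or uncertain.

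From the deposited intensity values log2 was taken. A probe set was kept where its mean log2 value was at least 5 (32 intensity units) in 1 population or both, which left 19342 of 45037. Populations were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend), with Benjamini-Hochberg adjustment over all kept probe sets. A probe set was called at an adjusted p below 0.05 and an absolute log2 fold change of at least 1. Adjusted p-values of genes are those of this fit over probe sets. Fold changes are TTP-GFP positive against TTP-GFP negative, with limma's SE and 95% interval. Where the dimmer population's mean lay under the floor, the fold is given as at least the brighter mean over the floor.

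Gene symbols came from the array annotation and were updated through gene identifiers with a table of the GRCm38.p6 annotation, used for names only and found for 34741 probe sets. On the array 34945 probe sets had 1 symbol, 932 had several and 9160 were unnamed here. A gene stood for its kept probe set of highest mean, and only probe sets with 1 symbol were named, which gave 9007 genes. No gene had probe sets called in opposite directions, though the size of the change can differ between probe sets of a gene.

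The gene lists, the floor, the thresholds, the tests and the rule for named genes were fixed before the data were examined. Named were Zfp36, Zfp36l1, Zfp36l2, Myc, Trp53, Cdkn1a, Cdkn2a, Ccnd1, Ccnd2, Ccnd3 and Bcl2 whatever their result. To these came the 12 called genes with the largest rise and the 12 with the largest fall, up to 4 called members per list with the largest change, and, for a list without a called member, up to 2 members of highest level. Of 27 lists, 22 had at least 5 kept members and were tested on the gene-level values with camera (preset correlation between genes of 0.01), camera with an estimated correlation and fry, each adjusted over the lists. The lists covered the TTP family, reported AU-rich targets, immediate early genes, mRNA decay, growth, cell cycle, p53, BCL-2 and B-cell genes. Others covered inflammatory, metabolic, stress and housekeeping genes and markers of other cell types. A planned search for AU-rich elements in 3′ untranslated regions was not run, since it needs transcript sequences that were not used here.

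Both populations carry replicate numbers 1 to 3. After subtracting population means, arrays of the same number correlated at 0.17, 0.36 and 0.3, all above 0.1, so the numbers were taken to pair the arrays, and the fit was repeated with the replicate number as a block. Other alternatives were no floor and floors of 3 and 7, eBayes with a trend and robust eBayes, and quantile normalization or median centring of the arrays. Thresholds were varied to adjusted p alone, a fold of 1.5 and limma's treat against a fold of 1.5. Each array was left out in turn, and probe sets were summarised per gene in other ways. A floor in both populations and cyclic loess normalization were added after seeing the data. The number of arrays, not a count of reads, limits the precision, and the median SE of a gene's log2 fold change was 0.121.

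The fit was tested on simulated data with the means and spreads of the 19342 kept probe sets and 200 changed ones. It called 56% of probe sets changed by a log2 fold of 1, 90% of those changed by 1.5 and 98% of those changed by 2, and 3 unchanged probe sets. A call needs an estimate of at least 1, and at adjusted p alone 88% of those changed by 1 passed. The simulated noise was independent between probe sets and arrays, unlike that of the arrays here. The 3 calls therefore give no rate of false calls for these data.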

Results

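Gene expression was measured in lymphoma cells of Eμ-Myc mice, in which the Myc oncogene is driven by an immunoglobulin heavy-chain enhancer and B-lineage tumours arise. The cells were grown outside the animal and first given a retrovirus for the red fluorescent protein dsRed2, and the red cells were kept. A retrovirus for tristetraprolin (TTP) linked to green fluorescent protein (GFP) followed, and the culture was sorted into TTP-GFP negative and TTP-GFP positive cells. TTP, encoded by Zfp36, binds AU-rich elements in the 3′ untranslated regions of messenger RNAs and promotes their decay. RNA of each sorted population was read on 3 whole-transcriptome Affymetrix mouse arrays, 6 in all, each with 45037 probe sets. The labels call the arrays of a population technical replicates, so every p-value below measures the spread between arrays and not between tumours, cultures or infections. The number of arrays limits the precision.

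The arrays parted by population. Pearson correlations of log2 intensity over the 19342 probe sets above the floor lay between 0.9886 and 0.9957 for the 6 pairs of arrays within a population. For the 9 pairs across populations they lay between 0.9685 and 0.9754. The first principal component held 70.8% of the variance and separated the populations. No pair of arrays held identical values. The median log2 intensity over these probe sets was 9.04, 8.90 and 8.84 on the TTP-GFP negative arrays and 8.86, 8.79 and 8.75 on the TTP-GFP positive arrays. Over all 45037 probe sets, most of them under the floor, the medians of the populations overlapped. They were 3.44, 3.36 and 3.33 on the TTP-GFP negative arrays and 3.35, 3.37 and 3.39 on the TTP-GFP positive arrays.

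The comparison asks which transcripts differ between cells sorted as positive and as negative for the TTP virus. No array held cells given a GFP virus without TTP. An effect of TTP therefore cannot be told apart from one of the second infection, of GFP or of how readily a cell is infected. For the transcript of TTP itself no difference was detectable, as the Zfp36 probe set read 412.5 ± 42.4 intensity units (SD, n = 3) in TTP-GFP negative cells and 389.8 ± 27.1 (SD, n = 3) in TTP-GFP positive cells. Its log2 fold change was -0.08, with a 95% confidence interval from -0.345 to 0.187 and an adjusted p of 0.626 in limma, and its sign turned with another array scaling (0.05 after centring each array on its median). Where this probe set lies relative to the Zfp36 sequence in the virus is unknown here, so it checks neither the labels nor the expression of the virus. Both of the other TTP family members measured had lower signals in TTP-GFP positive cells. Zfp36l2, which encodes another AU-rich element binding protein, went from 6656 ± 300 to 2589 ± 244 intensity units (SD, n = 3), a 2.58-fold fall (adjusted p = 0.000212). Its other probe sets were under the floor on all arrays. Zfp36l1 had log2 fold changes of -0.55 and -0.81 on its 2 probe sets (adjusted p = 0.00656 and 0.00112), below the fold threshold.

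In TTP-GFP positive cells 470 genes were called lower and 176 higher, of 9007 genes tested with 1 probe set each (adjusted p below 0.05 and at least a 2-fold difference). Over all probe sets the counts were 1069 lower and 306 higher, 77.7% lower. With each array centred on its median the counts were 727 lower and 461 higher probe sets (61.2% lower), and 320 lower and 257 higher genes (55.5% lower). Centring moved the median log2 fold change of all genes from -0.06 to 0.07, a shift of 0.13, and fold changes of single genes below should be read against that shift. In 61 of the 646 called genes the dimmer population lay under the floor of 32 intensity units, and their folds are given as lower bounds. An index of signal within genes also moved with the sort. In 4424 genes with several probe sets, the dimmest probe set lay a median 2.25 log2 units below the brightest in TTP-GFP negative cells (-2.251 ± 0.035, SD, n = 3). In TTP-GFP positive cells the value was -2.326 ± 0.03 (SD, n = 3), below every TTP-GFP negative array. The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 arrays allow. Within the pairs of the same replicate number the index differed by -0.08, -0.0707 and -0.0745 (mean -0.0751, SD 0.0046), lower in all 3 pairs. An exact sign-flip permutation over 3 pairs cannot go below p = 0.25, the value it gave. Every gene group below was compared between these same arrays.

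**Figure D1:**
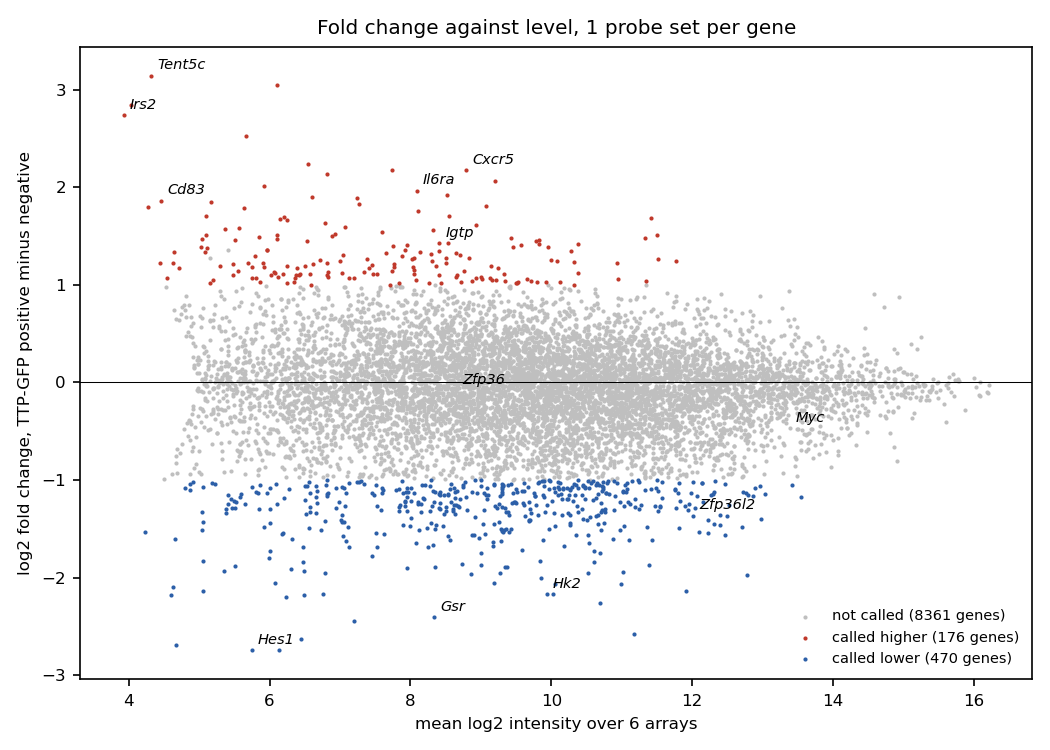
Log2 fold change (TTP-GFP positive minus TTP-GFP negative, vertical) against mean log2 intensity over the 6 arrays (horizontal), 1 point per gene and 1 probe set per gene. Red points are the 176 genes called higher and blue points the 470 called lower; Zfp36 lies at -0.08, while Cxcr5 at 2.18 and Gsr at -2.40 lie far from 0.

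The 12 genes with the largest falls had several known functions. Rpa3, a subunit of the single-stranded DNA binding complex RPA, fell 5.95-fold (adjusted p = 2.7e-05), from a log2 intensity of 12.46 ± 0.01 to 9.88 ± 0.05 (SD, n = 3). Gsr, the glutathione reductase, fell 5.30-fold (adjusted p = 0.00019), and at least 5.56-fold on its second probe set. Rpia, the ribose-5-phosphate isomerase of the pentose phosphate pathway, fell 4.50-fold (adjusted p = 0.000144), and Pfdn4, a subunit of the chaperone prefoldin, fell 4.79-fold (adjusted p = 8.55e-05). Rhobtb3 fell 6.20-fold, the zinc-finger factor gene Insm1 5.46-fold, Tmem158 4.59-fold and Acyp2 4.54-fold. On its second probe set Insm1 fell less (log2 fold change -0.90), and on that of Rhobtb3 the fall was at least 1.18-fold. Hes1, a transcriptional repressor downstream of Notch, was at least 4.35-fold lower, and Hopx at least 5.69-fold lower, with a log2 fold change of -1.35 on its second probe set. Scin, an actin-severing protein gene, and Sema5b were at least 2.02-fold and 1.62-fold lower.

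Of the 12 genes with the largest rises 6 were above the floor in both populations. Cxcr5, the receptor for the follicular chemokine CXCL13, rose 4.52-fold (adjusted p = 0.000151), from a log2 intensity of 7.70 ± 0.23 to 9.88 ± 0.16 (SD, n = 3). Fcrl1, a B-cell receptor of the Fc receptor-like family, rose 4.51-fold (adjusted p = 8.55e-05), P2ry10 4.19-fold (adjusted p = 0.00245) and Il6ra, the interleukin 6 receptor, 3.91-fold (adjusted p = 0.00036). Tnfaip8l2, a negative regulator of immune receptor signalling, rose 4.72-fold, and Castor2, of the family of CASTOR arginine sensors for mTORC1, 4.39-fold. The remaining 6 of the 12 largest rises began below the floor. Rhpn2 was at least 6.23-fold higher, Rdh12 at least 3.81-fold, Cyp39a1 at least 3.80-fold and Tent5c, a poly(A) polymerase gene, at least 1.85-fold. Csf2rb2, an interleukin 3 receptor beta subunit, and Irs2, an insulin receptor substrate, were at least 1.38-fold and 1.23-fold higher, with adjusted p of 8.55e-05 and 0.000144.

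Glycolysis and hypoxia genes showed the densest falls of any list tested. Of 28 members measured, 8 fell and none rose, and the count adjusted over the list alone was also 8. Hk2, the hexokinase that starts glycolysis in proliferating cells, fell 4.49-fold (log2 fold change -2.17 ± 0.14, SE). The mitophagy receptor gene Bnip3 fell 4.20-fold, Pfkfb3, which makes the activator of phosphofructokinase, 2.84-fold, and the glucose transporter gene Slc2a1 2.58-fold (adjusted p from 0.000144 to 0.000604). The list's median log2 fold change was -0.41, against -0.06 for all genes, and camera called the list lower (adjusted p = 0.0025). With an estimated correlation between genes the adjusted p was 0.991, as for nearly all lists tested.

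Myc-activated growth genes and ribosome biogenesis genes had median log2 fold changes of -0.34 and -0.35. Camera called both lists lower (adjusted p = 0.00044 for each). With an estimated correlation the adjusted p was 0.991 for each, so both calls rest on the preset correlation. The adjustment over the lists gave the same value to the ribosomal protein list with its median of -0.04. Of 44 measured growth genes, 2 fell and 1 rose past the fold threshold, with the same counts adjusted over the list alone. At adjusted p alone 26 were lower and 2 higher. The 2 that fell were Hk2 and Ppat, the first enzyme of purine synthesis (2.57-fold lower, adjusted p = 0.000205; log2 fold change -0.48 on its second probe set). The member that rose, Mxd4 (2.37-fold, adjusted p = 0.000589), encodes a MAX partner that represses Myc target genes. Of 50 ribosome biogenesis genes 1 fell, Ebna1bp2 (2.04-fold; log2 fold change -0.90 and no call after centring the arrays), and at adjusted p alone 29 were lower and 2 higher. Myc itself, at a log2 intensity of 13.62 ± 0.04 and 13.15 ± 0.07 (SD, n = 3), had a log2 fold change of -0.47 (adjusted p = 0.00724), which missed the fold threshold.

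Interferon-stimulated and NF-κB target genes had median log2 fold changes of 0.26 and 0.21. Camera called both lists higher with the preset correlation (adjusted p = 0.00515 and 0.0231) and neither with an estimated correlation (adjusted p = 0.991 for both), and fry called neither (0.0568 and 0.101). Fry was not run after centring, where the medians were 0.39 and 0.34. Of 21 interferon-stimulated genes 4 rose and none fell. Igtp, an interferon-induced GTPase gene, rose 2.69-fold (adjusted p = 0.000288), and the transcription factor gene Irf1 2.46-fold (adjusted p = 0.000459). Ifih1, the double-stranded RNA sensor MDA5, rose 2.33-fold (log2 fold change 0.90 and no call without TTP-GFP negative replicate 3; no call without a floor either, adjusted p = 0.0578). Gbp2 rose 2.15-fold (at least 2.65-fold on its second probe set), with no call without a floor (adjusted p = 0.098), without TTP-GFP negative replicate 3 (0.0548) or without TTP-GFP positive replicate 2 (log2 fold change 0.85). Of 20 NF-κB targets 3 rose and none fell. Nfkbie, which encodes the inhibitor IκBε, rose 2.68-fold (adjusted p = 0.00019), Tnip1, which encodes another brake on the pathway, 2.27-fold (adjusted p = 0.00149), and the activation marker Cd83 was at least 1.31-fold higher. Counts adjusted over each list alone were the same, 4 and 3. The NF-κB call was lost without a floor (0.0976), with a floor of 7 (0.0763), with the floor in both populations (0.0557) and after centring (0.0523).

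**Figure D2:**
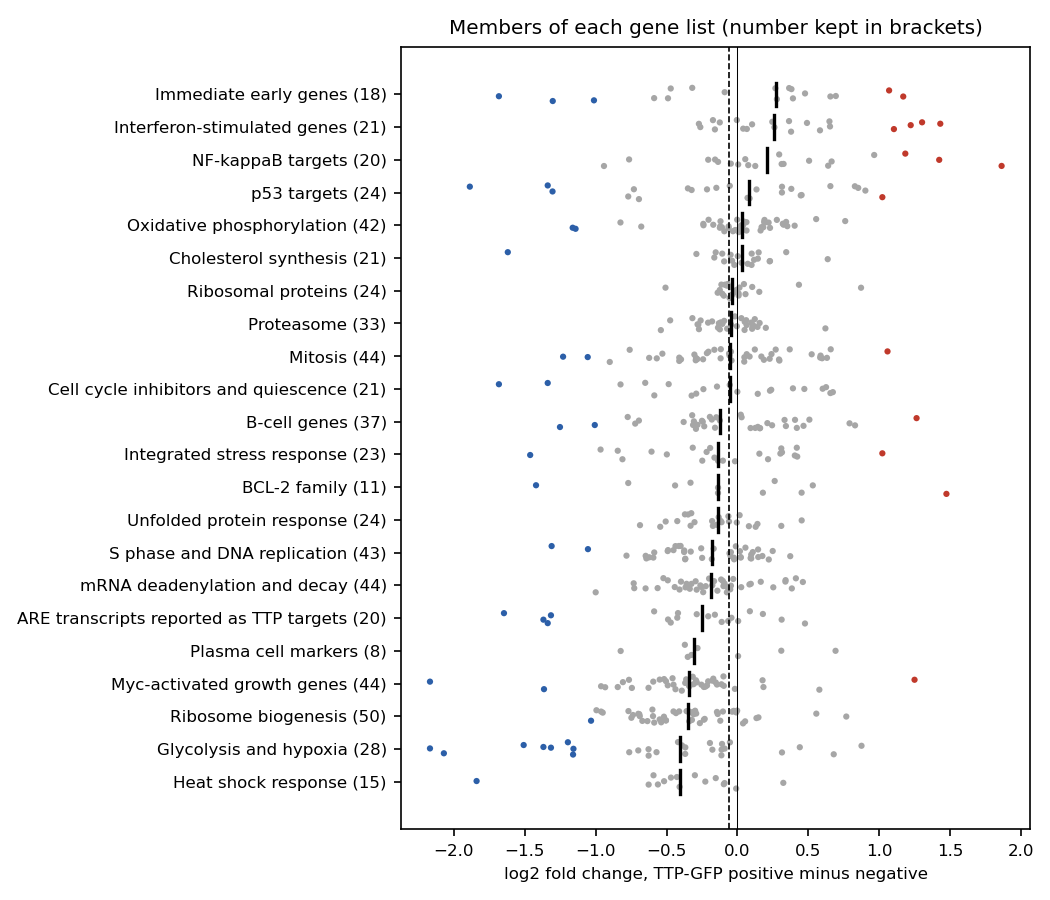
Log2 fold change (TTP-GFP positive minus TTP-GFP negative, horizontal) of the members of the 22 gene lists tested, 1 point per gene, red for genes called higher, blue for genes called lower and grey for the rest. Black bars are list medians, from -0.41 to 0.27, and the dashed line is the median of all genes at -0.06.

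Transcripts with AU-rich elements that are reported as TTP targets were measured for 20 of the 42 genes of that list. Of these 4 fell and none rose, also when adjusted over the list alone. Pim3, a serine/threonine kinase gene, fell 3.13-fold (adjusted p = 0.000197), Slc2a1 2.58-fold and Vegfa, the vascular endothelial growth factor, 2.49-fold (adjusted p = 0.000442). Cdkn1a, the cell cycle inhibitor p21, was at least 2.07-fold lower (adjusted p = 0.000205). The list's median of -0.25 did not differ from other genes in camera (adjusted p = 0.0993). The list was called lower in 3 of 15 other settings, without TTP-GFP positive replicate 2 (0.0385), with a floor of 3 (0.0371) and with the mean of probe sets (0.0481). Fry, which asks whether the members move one way and not whether they differ from other genes, gave an adjusted p of 0.0111. Among 18 immediate early genes, of which many carry AU-rich elements, 3 fell and 2 rose. Klf2 fell 3.21-fold (adjusted p = 0.000505) and Dusp2 2.47-fold (adjusted p = 0.000328), while Jun rose 2.25-fold (adjusted p = 0.000868). Dusp5 rose 2.10-fold, with no call without TTP-GFP negative replicate 1 (log2 fold change 0.94) or TTP-GFP positive replicate 2 (0.97). That list's median was 0.27 and its mean -0.01 (camera, adjusted p = 0.534). None of 44 genes for deadenylation and mRNA decay passed the fold threshold, and at adjusted p alone 12 were lower and 4 higher (camera, adjusted p = 0.28; called lower without a floor, 0.000111). Their brightest members had log2 fold changes of -0.09 for Hnrnpd (adjusted p = 0.509; down to -0.57 on its other probe sets) and -0.40 for Cnot6 (adjusted p = 0.0189).

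**Figure D3:**
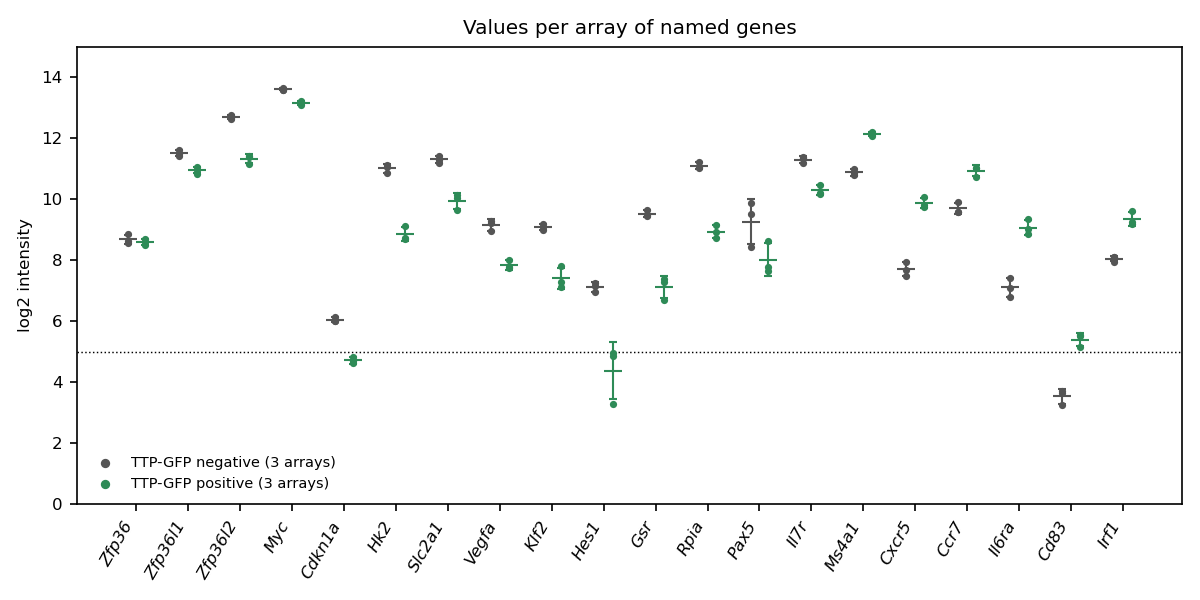
Log2 intensity (vertical) of 20 named genes on each array, grey for the 3 TTP-GFP negative and green for the 3 TTP-GFP positive arrays, with mean and SD; the dotted line is the floor at 5. Zfp36 overlaps between populations, while Hk2, Rpia, Cxcr5 and Ms4a1 do not.

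Cell cycle lists held few genes past the fold threshold. Of 43 genes of S phase and DNA replication 2 fell, the origin recognition subunit gene Orc6 (2.48-fold, adjusted p = 0.00017) and Tipin (2.08-fold), and at adjusted p alone 17 were lower and none higher. Tipin was not called without TTP-GFP positive replicate 3, where its fold fell just short of the threshold (adjusted p = 0.00206), or after centring (log2 fold change -0.92). Of 44 mitosis genes 2 fell and 1 rose. Mad2l1 of the spindle checkpoint fell 2.34-fold (adjusted p = 0.000228), Anln 2.08-fold, and the phosphatase gene Cdc25b rose 2.08-fold. Anln was not called without TTP-GFP negative replicate 2 (log2 fold change -0.97) or after centring (-0.93), and Cdc25b was not called without TTP-GFP negative replicate 3 (0.99) or TTP-GFP positive replicate 2, where its fold fell just short of the threshold (adjusted p = 0.00376). Of 21 cell cycle inhibitors and quiescence genes 2 fell, Klf2 and Cdkn1a, and none rose. Camera called none of these 3 lists (adjusted p = 0.155, 0.838 and 0.958). It called the S phase list lower without a floor (5.33e-05) and with a floor of 3 (0.046), and fry gave that list an adjusted p of 0.016. Fry gave the mitosis list 0.48 and the inhibitor list 0.109, and the medians of the mitosis and inhibitor lists changed sign with the array scaling. Among D-type cyclins, Ccnd3 had a log2 fold change of -0.86 on its brightest probe set and 0.67 on the other, Ccnd2 one of -0.44 (adjusted p = 0.00841) and Ccnd1 one of -0.29 (adjusted p = 0.106). Cdkn2a, at a log2 intensity of 13.18 in both populations, had a log2 fold change of 0.00 with an interval from -0.36 to 0.36 (adjusted p = 0.997).

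Of 24 p53 targets 3 fell and 1 rose. Rrm2b, the p53-induced ribonucleotide reductase subunit, fell 3.70-fold (adjusted p = 0.000197), Mdm2, the ubiquitin ligase for p53, 2.47-fold (adjusted p = 0.000476) and Cdkn1a at least 2.07-fold. Sesn2 was at least 1.58-fold higher, with no call without TTP-GFP negative replicate 2, TTP-GFP positive replicate 1 or TTP-GFP positive replicate 2. The list did not differ from other genes (camera, adjusted p = 0.68), and its median of 0.08 and mean of -0.06 differed in sign. Trp53 was not analysed here. In the BCL-2 family, with 11 members measured, the pro-death gene Bmf rose 2.77-fold (adjusted p = 0.000987) and the pro-survival gene Bcl2l2 fell 2.68-fold (adjusted p = 0.00035). Bcl2 had a log2 fold change of 0.18 (adjusted p = 0.624). The list did not differ from other genes (camera, adjusted p = 0.873).

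Of 37 B-cell genes 1 rose and 2 fell. Ms4a1, which encodes the mature B-cell antigen CD20, rose 2.40-fold (adjusted p = 0.000228). Pax5, the B-lineage commitment factor gene, fell 2.38-fold (adjusted p = 0.0412), with SDs of 0.75 and 0.54 between arrays. It was not called without TTP-GFP negative replicate 1 (log2 fold change -0.95) or 3 (-1.13), without TTP-GFP positive replicate 1 (-1.13) or 2 (-1.06), or after centring (-1.12), and neither without a floor (adjusted p = 0.193) nor with a floor of 3 (0.081). Il7r, the interleukin 7 receptor of early B cells, fell 2.01-fold (adjusted p = 0.000831; log2 fold change -0.68 on its second probe set). It lay below the fold threshold without TTP-GFP negative replicate 1 (-0.99) or 2 (-0.96), without TTP-GFP positive replicate 2 (-0.96) or 3 (-0.95), and after centring (-0.88). Camera did not call the list (adjusted p = 0.819), and its median changed sign with the scaling.

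Markers of other cells that a sort could hold were mostly under the floor. Of 21 T and NK cell markers 3 were measured and none passed the fold threshold. Cd2 had a log2 fold change of 0.94 (adjusted p = 0.00513) and Zap70 one of 0.52 (adjusted p = 0.0244). Cd2 was called higher after centring (1.07), without TTP-GFP negative replicate 1 (1.08) and without TTP-GFP positive replicate 3 (1.03). Of 28 myeloid markers 2 were measured, Ctss with a log2 fold change of 0.63 (adjusted p = 0.00223) and Mrc1 with -0.76 (adjusted p = 0.00681). Car2, with -0.57, was the only erythroid or megakaryocyte marker measured of 15, and Pecam1, with -0.77, the only fibroblast or endothelial marker of 25. Of 8 plasma cell markers measured none was called. The brightest were Mzb1 with -0.35 (adjusted p = 0.0565) and Tnfrsf13b with 0.00 (adjusted p = 0.979), and camera gave the list an adjusted p of 0.838.

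Stress and housekeeping lists held few calls. Of 15 heat shock genes 1 fell, Hspa1b of the HSP70 family (3.58-fold, adjusted p = 0.00117), and at adjusted p alone 8 were lower and none higher. The list median was -0.41, with a camera adjusted p of 0.0553, and 0.0482 with the replicate number as a block. Of 15 other settings 8 called the list (adjusted p from 0.000388 to 0.0894 over all 15), among them no floor (0.000388), a floor of 3 (0.0283), quantile (0.0212) and loess (0.0339) scaling and the mean of probe sets (0.034). Without TTP-GFP negative replicate 1 it was 0.0478 and without TTP-GFP positive replicate 2 it was 0.0395. In the integrated stress response list of 23 genes, the arginine transporter gene Slc7a1 fell 2.75-fold (adjusted p = 0.000476) and Sesn2 rose (camera, adjusted p = 0.868). No gene of the unfolded protein response was called among 24, and Hspa5 and Canx had log2 fold changes of -0.33 (adjusted p = 0.0737) and -0.15 (adjusted p = 0.262; down to -0.84 on another probe set), with a camera adjusted p of 0.534 for the list (called lower without a floor, 0.00378). Of 42 oxidative phosphorylation genes 2 fell, Uqcrfs1 of complex III (2.24-fold, adjusted p = 0.000557) and cytochrome c, Cycs (2.21-fold, adjusted p = 0.000293; -0.56 on another probe set). Of 21 cholesterol synthesis genes 1 fell, Hsd17b7 (3.07-fold, adjusted p = 0.000144). Camera called neither list (adjusted p = 0.534 and 0.661). None of 24 ribosomal protein genes and none of 33 proteasome genes was called (camera, adjusted p = 0.838 and 0.996). Rplp2 and Rpl35 had log2 fold changes of -0.11 and 0.01 (at least 1.25-fold lower on 1 other probe set of Rpl35 and up to 0.16 on the rest), and Psmb4 and Psma3 of -0.05 and -0.12, with adjusted p from 0.315 to 0.954. Camera called 5 of the 22 lists in all, 3 lower and 2 higher, fry 6, all lower, and camera with an estimated correlation none (unadjusted p under 0.05 in 0 lists). Fry does not compare with other genes and was not run after centring, which moved the median log2 fold change of all genes up by 0.13. That all its calls were lower may therefore rest on the array scaling. With the estimated correlation every tested list had an adjusted p of 0.991 or 0.999, values tied by the adjustment over the lists. With the preset correlation 7 lists had an unadjusted camera p under 0.05. The correlation was estimated from few arrays, so the lack of calls does not show that the lists were unshifted. The camera calls therefore rest on the preset correlation. In other splits of the 6 arrays, which mix the populations, camera with the preset correlation called up to 6 lists. Where such a split parted all pairs of replicate numbers it called up to 4. These splits still carry part of the sort difference, so they are no measure of calls without it. Adjusted over the list alone, counts past the fold threshold were those given in each of the 27 lists.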

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

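The probe set and gene counts stayed within 1.5 times their main values of 1375 and 646 under other floors, variance models, scalings, probe set summaries and the replicate block (1389 probe sets, 647 genes). They moved with the thresholds. Adjusted p alone gave 6785 probe sets and 3427 genes, a fold of 1.5 gave 4131 and 1963, and treat against 1.5 gave 824 probe sets and 438 genes, by construction of the thresholds. Leaving out 1 array gave 1226 to 1581 probe sets and 621 to 718 genes, and between 570 and 602 of the 646 main genes were called each time. After centring 496 of them were, and 257 genes were higher and 320 lower; quantile normalization gave 257 and 308, and cyclic loess, added after seeing the data, 246 and 335. No named gene that was called and no called list turned its direction under the alternatives run. Centring, quantile and loess scaling each ended the calls of the same 5 named genes, Ebna1bp2, Tipin, Anln, Pax5 and Il7r. Without a floor Pax5, Ifih1 and Gbp2 lost the call, with a floor of 3 or robust eBayes Pax5 did, and with the mean of probe sets Ppat, Il7r and Cycs, of which Ppat and Cycs also lost it without the probe sets marked s, x or a in the array's naming. Treat ended 8 named calls. Blocking by replicate changed the call of the heat shock list and of no other of the 22 lists, and no named gene's call. Of 22 lists, 5 were called, 8 without a floor, 8 with a floor of 3, and 0 with an estimated correlation; the cause was not tested. Zfp36 kept adjusted p from 0.451 to 1. The glycolysis, Myc growth, ribosome biogenesis and interferon lists were called under all 15 other settings of the values with the preset correlation. The AU-rich element search was not run. Signal over background limits genes near the floor: 61 called genes had 1 population under it.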

Other observations

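The tests on the 7 added lists, the symbol families, the share of lower calls, other cells, the splits of the arrays and the reading of Zfp36 were chosen only after the results were seen, as were the genes named from the added lists and families; the fit, the fixed lists, median centring and the Zfp36 fold change were planned. Lists of later and of early B-cell genes were made after calls in opposite directions had been seen among their members. Of 27 mature B-cell genes 5 rose and none fell: Cxcr5, Fcrl1, Cd83, Ms4a1 and Ccr7, the homing receptor for lymph nodes (log2 fold change 1.24). Of 19 genes listed for pro-B and pre-B cells, called early genes below though they need not be limited to these stages, 3 fell and none rose. The 3 were Pax5, Il7r and Bst1 (-1.45). Pax5 and Il7r each lost the call in 4 of 6 fits without 1 array, with the values given in the report, and under all 3 other scalings, and Bst1 in none. Abundant mature genes went both ways, with 0.47 for Cd74, 0.51 for H2-Aa (1.15 and called higher on its second probe set), 0.10 for Fcgr2b, 0.00 for Tnfrsf13b, -0.32 for Cd22 (adjusted p = 0.0515) and -0.44 for Ly86 (adjusted p = 0.0129). The surrogate light chain genes Igll1 and Vpreb1 had -0.31 each (adjusted p = 0.0505 and 0.0562). Since the lists held genes that had prompted them, those were left out for the test. Among them were all 5 mature genes that rose, and Pax5 and Il7r. None of the remaining 20 mature genes was called, and of the remaining 17 early genes only Bst1 was called, lower. The remaining 20 mature genes were shifted up in camera (median 0.15, adjusted p = 0.0344 over 7 such lists) and the remaining 17 early genes down (median -0.31, adjusted p = 0.0378; 0.0535 with the replicate block). With an estimated correlation, which called no added list, both adjusted p were 0.682, so both shifts rest on the preset correlation.

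Of 61 lysosome and autophagy genes measured 6 rose and 1 fell, and all 6 that rose had prompted the list. The rises included the acid sphingomyelinase gene Smpd1 (1.71), the autophagy initiation gene Rb1cc1 (1.46), Atg16l2 (1.25) and Atg9a (1.21), and the acid ceramidase gene Asah1 fell (-1.01; no call without TTP-GFP negative replicate 1 or TTP-GFP positive replicate 2, or after centring). Without the 6 members seen before, none of the other 55 was called higher and 1, Asah1, was called lower. As a set the 55 were shifted up (median 0.25, camera adjusted p = 0.00267, and 0.682 with an estimated correlation). Targets of FOXO transcription factors went both ways. Irs2, Bmf, Pik3ip1 (1.34), Ccr7, Fbxo32 (at least 1.24-fold) and Sesn2 rose, and Klf2, Bnip3, Cdkn1a, Sod2 (-1.29) and Il7r fell, and the 20 members not seen before had a median of 0.47 (adjusted p = 0.0268; 0.682 with an estimated correlation). Of 26 genes of the pentose phosphate pathway and purine synthesis 3 fell, Rpia, Ppat and Pfas (-1.48), and the 23 tested, without Rpia, Ppat and Hprt, which had been seen before, but with Pfas, were shifted down (median -0.22, adjusted p = 0.0342; 0.682 with an estimated correlation). Negative results stood beside these. The list of NRF2 targets without Gsr and the other members seen before was not called (16 genes, median -0.06, adjusted p = 0.777), with 1 member higher, Gstm1 (1.19; no call without any 1 of 3 arrays), and 1 lower, Abcc1 (-1.25). Of 28 cytokine and chemokine receptors 7 rose, Csf2rb2, Il6ra, Cxcr5, Il10ra (at least 2.14-fold), Csf2rb (1.68), Ccr7 and Il5ra (1.22; no call without TTP-GFP negative replicate 3), and 3 fell, Il15ra (-1.43), Il1rap (-1.10; no call after centring) and Il7r. The whole list was called higher (adjusted p = 0.0214; 0.458 with an estimated correlation), and the 18 not seen before, without the members that prompted the list, were not, with a median of 0.00 and an adjusted p of 0.777. Among 70 families of genes that share a symbol stem, only the intraflagellar transport genes passed (13 genes, median 0.44, adjusted p = 0.0151; 0.997 with an estimated correlation), with Ift81 (1.51) and Ift74 (1.12) called higher. Of the 7 added lists without the members seen before, fry called the early B-cell list (adjusted p = 0.0067) and the pentose phosphate and purine list (0.0406), and none of those shifted up (0.0625 to 0.516). Fry was not run after centring, which moved the median log2 fold change of all genes up by 0.13, so this split by direction may rest on the scaling. The shifts of the added lists and of the intraflagellar transport family are hypotheses for a test on other cultures.

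Array scaling may account for much of the excess of lower calls, since after centring 61.2% of called probe sets were lower in place of 77.7%. That is still above 50% (Wilson interval 58.39 to 63.93, for counting only, and 55.4 without TTP-GFP positive replicate 1), so scaling alone leaves an excess. Signal lost in the dimmer probe sets of a gene, as from RNA quality or labelling, leaves 72.8% lower among genes at their brightest probe set. Only 4424 of the 9007 genes had several kept probe sets. For the rest the choice of the brightest tests nothing, so a loss of signal stays possible there. Background near the floor leaves 82.3% lower among probe sets with a mean log2 intensity over all arrays of at least 7. The share rose with brightness, from 80.6% at a mean of at least 6 to 87.9% at one of at least 9. These shares were taken before centring, so array scaling may make up part of them. Scaling together with the loss in dimmer probe sets stays open, since brightest probe sets and centring left 55.5% of genes lower (Wilson interval 51.38 to 59.47) and 51.8% without TTP-GFP negative replicate 2 (interval from 47.74). A loss of mRNA in cells with TTP is a biological reading that stays untested, because centring would remove it too and the search for AU-rich elements was not run.

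The genes called higher, lymphocyte receptors among them, could come from other cells in the sort, but of 103 markers of T and NK, myeloid, erythroid, endothelial, fibroblast and plasma cells on the array, 0 were called higher and 88 lay under the floor in both populations, and 8 of the 15 above it were plasma cell markers. Against this, Cd2 had 0.94 and was called higher after centring (1.07), and the 3 measured T and NK markers had a median of 0.52. The median T and NK marker had a log2 intensity of 2.29 in TTP-GFP positive cells and the median myeloid marker 2.22, which argues against these cell types as the source of the higher calls as a whole. A larger share of more mature B cells among the TTP-GFP positive cells stays open, since the mature B-cell genes not seen before had a median of 0.152, and a change within the tumour cells would give the same sign, so the explanations cannot be told apart.

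The similar Zfp36 signal in cells sorted for and against the TTP virus stays unexplained. The probe set may lie outside the sequence that the virus carries, and its log2 fold change of -0.0789 then says nothing about TTP. Exchanged labels could not be tested by it either (adjusted p = 0.626). If the probe set does read the viral transcript, its interval with the deposited scaling ends at a 1.14-fold rise. After centring the log2 fold change was 0.05, so that end may lie higher. The cells sorted as TTP-GFP positive may in that case not carry more of the viral transcript, which would change the meaning of every comparison here. These explanations cannot be told apart without the probe and virus sequences.

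With 3 arrays against 3 there are 10 splits of the arrays, too few for a share under 0.05. The real split gave 1375 called probe sets and 646 called genes and was the only 1 of the 10 splits with as many, and the highest of the others gave 0 in each case. For the 22 lists camera with the preset correlation called 5 in the real split and up to 6 in another, and 3 of the 10 splits gave at least 5. Among the 4 splits that part all pairs of replicate numbers, the others called 0 probe sets and up to 4 lists. Every other split holds an uneven mix of both populations on each side, so it still carries part of the sort difference. The list counts of these splits therefore cannot show whether the calls with a preset correlation stand out. In such splits the sort difference also adds to the spread within each side. Their 0 called probe sets and genes therefore lend no weight to the real split. Probe sets unnamed here had a median log2 fold change of -0.198 (2275 kept), against -0.0883 for those with 1 symbol.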
